A study of Mus musculus with 6 samples.

How the data were processed

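Bulk RNA sequencing of 6 libraries of cultured mouse cortical astrocytes was analysed, 3 from knockout pups carrying Cre under the Gfap promoter and floxed Neo1 and 3 from littermate controls. RNA was extracted with Trizol and libraries were made with poly-T beads, which select polyadenylated RNA, per the labels' protocols. Reads were processed with HISAT2 2.2.1 and featureCounts 2.0.6 on the mouse genome build GRCm38 (mm10), per the submitters' processing notes. The deposited table holds raw counts per gene, whole numbers with no normalisation, for 54532 Ensembl gene identifiers in 6 columns. The annotation release, the strand setting and the rule for reads that map to several places are not given in the sources used here. Each of these can change counts: reads of a gene and its antisense neighbour cannot be told apart without strand, and genes with near-identical copies can lose reads or share them. Gapdh, which has many pseudogenes and is named outside the rule given below, was at 13.9 ± 3.29 CPM in control and 25.5 ± 10.6 CPM in knockout cultures (SD, n = 3).

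Columns were assigned to libraries by their names, which match the library names in the labels, and groups were taken from the labels' titles. Total counts ran from 60819277 to 106081115 per library. Any 2 libraries of one group differed by more than sampling noise (chi-square per gene from 5.996 to 22.2), so none was treated as a duplicate. Gene symbols, types and coordinates came from the GENCODE annotation of the same build, which held 54409 of the 54532 identifiers; the other 123 kept their identifiers. Of all genes, 32515 had a count in any library and 18530 passed edgeR's filterByExpr by genotype (minimum count 10, minimum total 15), holding 99.96% of counts.

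Differences between genotypes were tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, glmQLFit with the robust option and glmQLFTest on a model with genotype alone, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values use TMM-adjusted library sizes. Standard errors of log2 fold changes were computed from the test statistic. No pairing of replicate numbers was used.

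The 28 gene lists were fixed before the data were examined, as were the grouping, the tests, all but one of the other settings tried and the rule for naming genes. They were angiogenic factors, HIF subunits and regulators, hypoxia-responsive genes, glycolysis, phagocytic receptors and adaptors, lysosome, neogenin ligands and related receptors, BMP-SMAD target genes, YAP-TEAD target genes, cholesterol synthesis, astrocyte markers, pan-reactive, neuroinflammatory reactive and ischaemic reactive astrocyte genes, astrocyte synapse-regulating factors, basement membrane and matrix, interferon-stimulated genes, proliferation, immediate-early genes, and markers of neurons, the oligodendrocyte lineage, microglia and macrophages, endothelium, pericytes and smooth muscle, fibroblasts and meninges, ependyma and neural progenitors, with the Y-linked genes and Xist. A further 6 lists were written after the largest changes had been seen: choroid plexus markers, chemokines and cytokines, interferon-inducible GTPases, antigen processing for MHC class I, matrix metalloproteinases and ribosomal proteins. Each list was compared with all other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the 28 lists. For the 6 added lists only counts and medians are given, because they were chosen with the changes in view. Camera was repeated with the correlation estimated from the data, and fry was run as a test of whether a list moves one way, without comparison to other genes. With the preset correlation, camera takes its p-values on degrees of freedom set by the number of genes. With an estimated one, they are the far fewer left by the 6 libraries.

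Genes were named by rule: Neo1; Hif1a, Epas1, Vegfa and Megf10; the 10 largest rises and 10 largest falls among called protein-coding genes with a mean log2 CPM of at least 1 and no overlap between the groups; and up to 4 called members of each list with the smallest p. Genes named outside this rule are said to be so. Near-identical copies were searched with BLAST 2.17.0 of the longest transcript against all annotated transcripts (at least 95% identity over at least 100 bases), and overlapping exons were taken from the annotation.

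Alternatives were median-of-ratios and upper-quartile normalisation, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, a fit without the robust option, a replicate block, each library left out in turn, a threshold of 0.01, a test against a fold of 1.5, camera with estimated correlation and fry. Under DESeq2, lists were tested by the pre-ranked form of camera on the DESeq2 test statistics, with the same preset correlation. Scaling by total counts was added after the data were seen. The closing section gives their effect. The procedure was tested on simulated data: counts were drawn, each gene independently, for the 18530 genes at the real means, spreads and library sizes, with 50 genes each changed 1.1, 1.25, 1.5 and 2-fold and 1 list of 20 other genes raised 1.5-fold, and 18050 genes passed the filter. It recovered 4%, 26%, 44% and 74% of the genes changed by each fold, none of them in the wrong direction, and called 2 of the 17836 unchanged genes tested. Camera called the raised list and 0 of 20 lists drawn at random from genes outside those 4 sets. Of genes at a mean log2 CPM of at least 1, it recovered 94.9% of those changed 2-fold. A far smaller share of genes was changed here than was called in the real data, so the adjusted threshold was stricter. These rates may therefore understate the recovery of the reported fit. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.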

Results

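RNA sequencing had been done on primary astrocytes cultured from the cortex of mouse pups. Knockout cultures came from pups in which Cre recombinase driven by the promoter of Gfap, an astrocyte filament gene, deletes a floxed Neo1 gene, and control cultures came from littermates, per the study's design statement. The control samples are labelled only as control, and their library names point to the floxed gene without Cre. Neo1 encodes neogenin, a receptor for netrins and repulsive guidance molecules. The deposited table held raw read counts for 54532 genes in 6 libraries, 3 per genotype. Total counts were 60819277, 67365100 and 106081115 in control replicates 1, 2 and 3, and 97453331, 75255222 and 74614772 in knockout replicates 1, 2 and 3. The number of genes with at least 1 count ran from 22076 in knockout replicate 2 to 25767 in knockout replicate 1. The first principal component held 49.3% of the variance and separated the genotypes. The second held 19.6% and set knockout replicate 2 apart from knockout replicates 1 and 3. The labels call the libraries biological replicates but name no pup, litter or culture, so the p-values measure the spread between these samples, which may be partly technical.

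The question named by the study's title is whether astrocytic neogenin sets the balance between HIF and VEGFA driven angiogenesis and MEGF10 driven phagocytosis. Neo1 itself was lower in the knockout cultures, and so was Megf10, an engulfment receptor of astrocytes. Hif1a and Epas1, which encode the oxygen-regulated subunits HIF-1α and HIF-2α, were higher, as was Vegfa, a growth factor for blood vessels. These are RNA levels, and neither protein nor the activity of HIF was measured here. Camera did not call the lists of HIF subunits and regulators (adjusted p = 0.94), angiogenic factors (0.72), hypoxia-responsive genes (0.084) or phagocytic receptors and adaptors (0.72). Interferon-stimulated genes were higher as a group, while markers of microglia, most astrocyte markers and genes of cell division were lower. With the correlation between genes estimated from the data, camera called none of the interferon, microglia, astrocyte and cell division lists. That form of camera also has fewer degrees of freedom. Its adjusted p was 0.084 for the interferon, microglia and astrocyte lists and 0.11 for cell division. The estimated correlation was −0.013 for microglia markers and 0.014 for astrocyte markers, near the preset of 0.01. This argues against correlated members as the cause of those losses. The estimate was 0.17 for interferon-stimulated genes and 0.038 for cell division. Values below are normalised counts (CPM, with TMM normalisation) as mean ± SD (n = 3), with log2 fold changes of knockout over control, and a gene is said to have risen or fallen only where its adjusted p was under 0.05.

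Neo1 (ENSMUSG00000032340, GRCm38 chromosome 9, 58874687 to 59036441, minus strand) fell from 192 ± 5.20 to 104 ± 2.69 CPM, a fold of 0.540. Its log2 fold change was −0.89 (SE 0.05, adjusted p = 5.8e-11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and all 3 knockout libraries lay below all 3 control libraries. The count pools reads over every exon of the gene and the labels do not name the deleted exon, so it does not measure the deletion itself. Hif1a (ENSMUSG00000021109, chromosome 12, 73901375 to 73947530) rose from 231 ± 8.79 to 276 ± 12.4 CPM, with a log2 fold change of 0.26 (SE 0.05) and an adjusted p of 2.7e-04 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its exons overlap those of an antisense gene, Gm15283, and of Gm49321, and the strand setting of the counting is not given in the sources used here. Epas1 (ENSMUSG00000024140, chromosome 17, 86753700 to 86833410) rose from 142 ± 4.55 to 181 ± 1.75 CPM and Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369) from 111 ± 3.20 to 165 ± 5.13 CPM. Their log2 fold changes were 0.35 (SE 0.04) and 0.57 (SE 0.05), with adjusted p-values of 7.6e-06 and 3.1e-08 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Megf10 (ENSMUSG00000024593, chromosome 18, 57133090 to 57297467) fell from 67.3 ± 6.33 to 47.0 ± 0.880 CPM, a log2 fold change of −0.52 (SE 0.06, adjusted p = 5.1e-06, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

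**Figure D1:**
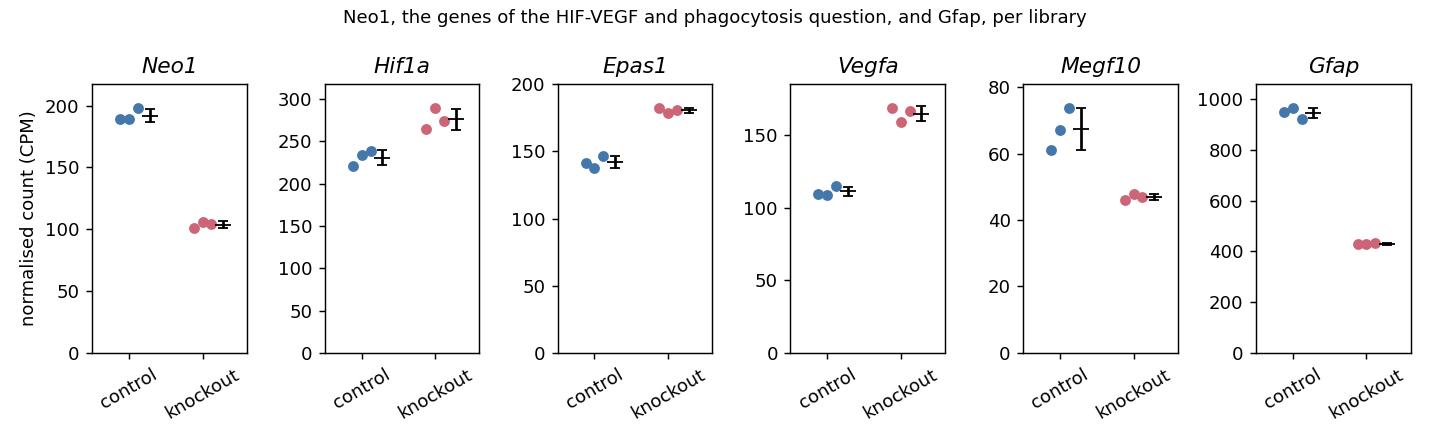
Normalised counts (CPM, vertical axes starting at 0) of Neo1, Hif1a, Epas1, Vegfa, Megf10 and Gfap in each control (blue) and knockout (red) library; black marks are means ± SD (n = 3). In each of the 6 panels the knockout libraries lie on one side of the control libraries, below for Neo1, Megf10 and Gfap and above for Hif1a, Epas1 and Vegfa.

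Of 18530 genes tested, 3627 were higher and 3466 lower in the knockout cultures (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Scaled by total counts alone, the split was 2921 higher and 4499 lower, and without knockout replicate 2, which lay apart from the other 2 knockout libraries on the second principal component, it was 3496 and 3431. Most changes were small: 2243 of the higher and 2461 of the lower genes differed by under 1.5-fold, and 745 and 365 by at least 2-fold. Against a minimum fold of 1.5, 666 genes were higher and 348 lower. Knockout and control libraries did not overlap for 9129 genes (49.3%, against 10% by chance), of which 6924 were called.

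Among called protein-coding genes with a mean log2 CPM of at least 1 and no overlap between the groups, the 10 largest rises and 10 largest falls are given here. Cxcl5, which attracts neutrophils, rose from 49.8 ± 2.47 to 453 ± 32.9 CPM (log2 fold change 3.19), and Cxcl9, which attracts T cells, from 5.28 ± 0.438 to 43.3 ± 1.74 CPM (3.03). The guanylate-binding protein genes Gbp4 and Gbp10 rose from 25.7 ± 1.55 to 212 ± 20.1 CPM and from 4.03 ± 0.629 to 32.7 ± 3.22 CPM, with log2 fold changes of 3.04 and 3.01. Gbp10 is uncertain, since 97.8% of its transcript aligns to Gm43302 at 99.2% identity. Grem1, which encodes an antagonist of bone morphogenetic proteins, rose from 15.8 ± 0.733 to 127 ± 8.15 CPM (3.00). F830016B08Rik rose from 3.97 ± 0.885 to 44.3 ± 2.63 CPM (3.46), Heatr9 from 1.18 ± 0.168 to 9.12 ± 1.06 CPM (2.95) and Ms4a4d from 0.745 ± 0.237 to 5.52 ± 0.238 CPM (2.89). The prolactin-family gene Prl2c2 rose from 1.57 ± 0.308 to 21.6 ± 0.464 CPM (3.78) and Prl2c3 from 0.296 ± 0.0779 to 6.06 ± 4.79 CPM (4.38). Prl2c2 and Prl2c3 are near-identical (99.5% over 842 bases), so reads may be split between them, and the log2 fold change of Prl2c3 was 3.50 without knockout replicate 2.

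Ttr, which encodes the thyroid hormone carrier transthyretin, had the largest fall. It had 1219, 1353 and 2048 counts in the control libraries and 1, 0 and 2 in the knockout libraries, a ratio of control over knockout of 1555 (95% confidence interval 532 to 7543, exact Poisson, counting error only). Its log2 fold change was −10.44, and −11.34 without knockout replicate 3. Whether the groups differ in sequence at Ttr was not examined, since the reads were not used here. The class I histocompatibility gene H2-Q1 fell from 4.02 ± 0.632 to 0.108 ± 0.0275 CPM (−5.20); it shares 96.2% identity with H2-Q2 over 921 bases. Gm11361, a near-identical copy of the ribosomal protein gene Rps18, fell from 58.7 ± 3.02 to 5.13 ± 0.926 CPM (−3.51), and Eno1b, a near-identical copy of the glycolytic enzyme gene Eno1, from 147 ± 9.38 to 16.1 ± 1.12 CPM (−3.19). Both are uncertain for that reason. Complement genes C1qa and C1qb fell from 7.53 ± 0.714 to 1.72 ± 0.650 CPM and from 11.5 ± 0.619 to 2.93 ± 0.678 CPM (−2.13 and −1.98), and the chemotactic receptor genes C5ar1 and Fpr1 from 8.68 ± 0.299 to 1.89 ± 0.0717 CPM and from 9.60 ± 1.31 to 2.22 ± 0.489 CPM (−2.20 and −2.10). Acta1, skeletal muscle actin, fell from 6.68 ± 0.871 to 1.58 ± 0.306 CPM (−2.09), and the protease-activated receptor gene F2rl1 from 67.0 ± 0.995 to 16.0 ± 1.90 CPM (−2.07).

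**Figure D2:**
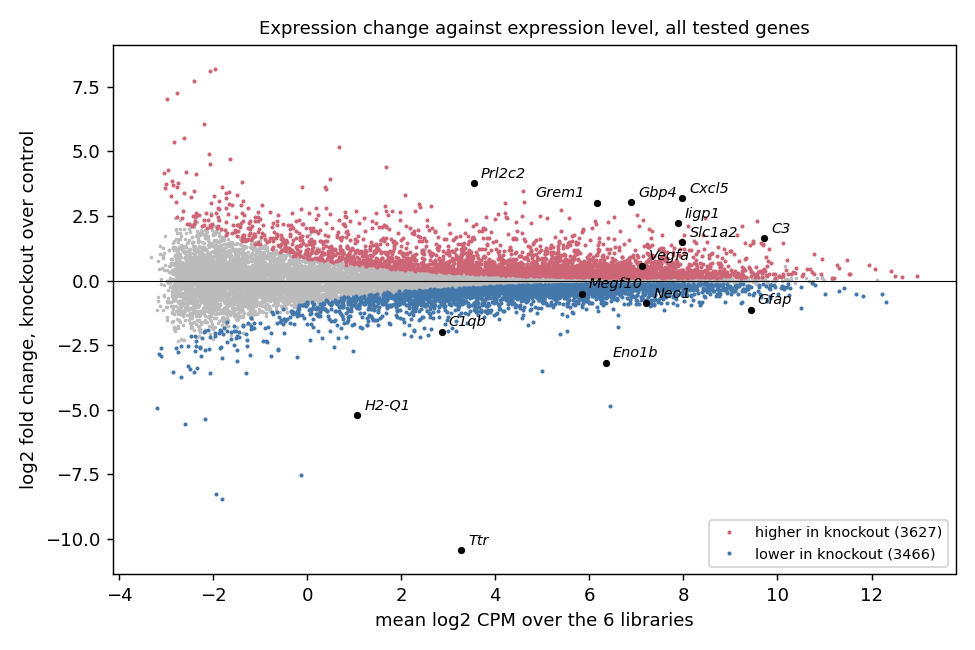
Log2 fold change of knockout over control against mean log2 CPM over the 6 libraries for the 18530 genes tested, with 3627 genes called higher in red, 3466 called lower in blue and the rest in grey. Of the labelled genes, Ttr and H2-Q1 lie lowest and Prl2c2 and Cxcl5 highest; the fold of Ttr rests on 3 counts in all over the 3 knockout libraries.

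In the 28 gene lists fixed before the data were examined, each list was compared with all other genes by camera, with Benjamini-Hochberg adjustment over the lists. By this test 6 lists were higher and 6 lower; with the correlation estimated from the data camera called 0 (8 at an unadjusted p under 0.05), and those adjusted p-values are given beside each called list. By fry, which asks whether a list moves one way and not whether it differs from other genes, 21 were called. Under total-count scaling the medians were −0.089 for angiogenic factors, 0.072 for hypoxia-responsive genes, −0.15 for glycolysis, −0.11 for phagocytic receptors and adaptors, −0.082 for YAP-TEAD target genes, 0.056 for astrocyte synapse-regulating factors and −0.078 for neural progenitor markers, each over 1.5 times from the value below. Where no separate figure is given, the number of members called when adjusted over the list alone was the same.

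Angiogenic factors moved in both directions. Of 25 measured, 11 rose and 9 fell (12 and 9 adjusted over the list alone), with a median log2 fold change of −0.02, a mean of 0.02 and a test direction upward (camera adjusted p = 0.72). The sign of this median turned positive under limma-voom, under a stricter filter, with a replicate block, and without control replicate 2 or knockout replicate 2. Beside Vegfa, the epidermal growth factor family member Ereg rose from 131 ± 6.46 to 221 ± 4.23 CPM, while Pdgfb, a recruiter of pericytes, fell from 343 ± 14.1 to 232 ± 8.69 CPM and the matricellular gene Cyr61 from 1450.3 ± 40.5 to 984 ± 25.1 CPM. HIF subunits and regulators split into 4 higher and 4 lower of 13, with a median of 0.03, a mean of −0.04 and a downward test direction (camera adjusted p = 0.94); the median was −0.031 under total-count scaling, −0.0092 without control replicate 2 and −0.011 without knockout replicate 3. Egln1, the oxygen-sensing hydroxylase that marks HIF for degradation, fell from 89.7 ± 1.36 to 58.0 ± 1.31 CPM, and Arnt2, a HIF partner, from 414 ± 20.1 to 322 ± 14.95 CPM. Hypoxia-responsive genes numbered 11 higher and 6 lower of 34 (12 and 6 adjusted over the list alone; median 0.14, camera adjusted p = 0.084, and 0.043 with no filter). Lox, a collagen cross-linking enzyme, rose from 607 ± 25.7 to 1128 ± 28.4 CPM. Glycolysis genes numbered 3 higher and 10 lower of 22 (4 and 10 adjusted over the list alone; median −0.08, camera adjusted p = 0.084, and 0.0074 on DESeq2 values, 0.039 on limma-voom values and 0.037 without control replicate 3). Pfkp fell from 221 ± 2.72 to 129.8 ± 1.80 CPM, Aldoc from 103 ± 2.84 to 56.7 ± 0.679 CPM and Ldhb from 307 ± 9.16 to 224 ± 7.23 CPM, while Pfkfb3 rose from 72.0 ± 3.94 to 103 ± 2.77 CPM; 76.8% of the Ldhb transcript aligns to Gm5514 at 98.0% identity.

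Phagocytic receptors and adaptors also moved both ways, 10 higher and 12 lower of 30 (11 and 12 adjusted over the list alone; median −0.05, camera adjusted p = 0.72). Itgb3, an integrin subunit, rose from 23.9 ± 2.68 to 48.6 ± 1.32 CPM and the complement gene C4b from 19.4 ± 2.88 to 41.2 ± 1.12 CPM, though C4b is 96.0% identical to C4a over its length. The receptor genes Adgrb1 and Stab1 fell from 34.6 ± 1.98 to 13.8 ± 2.16 CPM and from 16.8 ± 1.36 to 7.14 ± 0.501 CPM. Microglia and macrophage markers fell beside this list, 18 of 23. Lysosome genes numbered 11 higher and 9 lower of 35 (12 and 9 adjusted over the list alone; median 0.06, −0.0086 under total-count scaling, 0.034 without control replicate 3 and 0.026 without knockout replicate 2; camera adjusted p = 0.45). Npc2, a cholesterol carrier of the lysosome, rose from 226 ± 7.98 to 347 ± 10.1 CPM, and the protease gene Ctsk from 11.4 ± 0.952 to 28.5 ± 3.38 CPM.

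Among 16 neogenin ligands and related receptors, 9 rose and 4, Neo1 among them, fell (median 0.20, or 0.015 with no filter; camera adjusted p = 0.47). Ntn4, a netrin, fell from 75.9 ± 0.246 to 39.3 ± 1.73 CPM, the netrin receptor gene Unc5c rose from 28.3 ± 1.66 to 52.3 ± 3.94 CPM and the BMP receptor gene Bmpr2 from 169 ± 16.4 to 230.2 ± 8.70 CPM. BMP-SMAD target genes numbered 4 higher and 6 lower of 19 (4 and 8 adjusted over the list alone), with a median of −0.15, a mean of 0.01 and a downward test direction (camera adjusted p = 0.51); the median was −0.049 without knockout replicate 2. Grem1 rose, as given above, and Zcchc12 and Bmp4 fell from 5.16 ± 0.269 to 2.29 ± 0.364 CPM and from 6.39 ± 0.560 to 3.51 ± 0.685 CPM. YAP-TEAD target genes numbered 6 higher and 10 lower of 25 (6 and 11 adjusted over the list alone; median −0.02, camera adjusted p = 0.41, and 0.041 on DESeq2 values). This median turned positive without control replicate 3 or knockout replicate 2. Members that fell included F3, tissue factor, from 773 ± 15.4 to 428 ± 12.6 CPM and Ajuba from 138 ± 4.53 to 85.6 ± 4.29 CPM. Cholesterol synthesis genes were lower as a group, 1 higher and 12 lower of 24 (median −0.13, camera adjusted p = 0.0048; adjusted p = 0.11 with an estimated correlation). Pmvk, a kinase of the mevalonate pathway, fell from 56.4 ± 3.03 to 30.3 ± 2.25 CPM, and Srebf2, the transcription factor gene of the pathway, from 346 ± 3.61 to 272 ± 19.2 CPM.

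Astrocyte markers were lower as a group. Of 27, 2 rose and 18 fell (3 and 18 adjusted over the list alone; median −0.38, camera adjusted p = 8.3e-06; adjusted p = 0.084 with an estimated correlation). Gfap fell from 946 ± 20.8 to 431 ± 3.85 CPM (−1.13), the thyroxine transporter gene Slco1c1 from 39.7 ± 1.83 to 12.1 ± 0.775 CPM (−1.72) and Fgfr3 from 66.1 ± 1.41 to 25.5 ± 2.21 CPM (−1.37). The 2 that rose were Slc1a2, the glutamate transporter GLT-1, from 133 ± 8.41 to 371 ± 16.6 CPM (1.48), and the water channel gene Aqp4 from 605 ± 35.5 to 879 ± 31.2 CPM (0.54), the latter named after its values were seen. Markers of other cells moved beside this list: fibroblast and meningeal markers were 11 higher and 3 lower of 17 (median 0.59), and microglia and macrophage markers 1 higher and 18 lower of 23 (median −0.92), with their tests below. Pan-reactive genes numbered 9 higher and 3 lower of 13 (median 0.46, camera adjusted p = 0.021; adjusted p = 0.25 with an estimated correlation). Lcn2 rose from 432 ± 19.3 to 1168 ± 48.7 CPM, Cp, ceruloplasmin, from 385 ± 18.1 to 1046 ± 50.1 CPM and Serpina3n from 170.3 ± 3.29 to 385 ± 9.25 CPM, whereas Gfap, a member of this list too, fell. Neuroinflammatory reactive genes numbered 9 higher and 1 lower of 12 (median 0.86, camera adjusted p = 3.1e-05; adjusted p = 0.084 with an estimated correlation). The complement gene C3 rose from 406 ± 3.99 to 1267 ± 50.7 CPM, Iigp1 from 82.7 ± 1.01 to 388 ± 29.6 CPM, Gbp2 from 457 ± 16.0 to 1208 ± 9.81 CPM and H2-D1 from 151 ± 5.51 to 443 ± 31.1 CPM. Ischaemic reactive genes numbered 2 higher and 6 lower of 11 (median −0.16, −0.10 with no filter; camera adjusted p = 0.11). Ptgs2, cyclooxygenase 2, rose from 1144 ± 49.96 to 2349.7 ± 111 CPM, and Clcf1 and Tgm1 fell from 171 ± 3.63 to 102 ± 4.64 CPM and from 126 ± 1.65 to 80.2 ± 6.74 CPM.

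Matrix genes rose more often than they fell. Basement membrane and matrix genes numbered 15 higher and 5 lower of 27 (16 and 5 adjusted over the list alone; median 0.28, camera adjusted p = 0.0048; adjusted p = 0.35 with an estimated correlation). Nid1, nidogen, rose from 315 ± 18.7 to 696 ± 14.3 CPM, and the protease genes Mmp9 and Adamts4 from 5.74 ± 0.791 to 31.9 ± 2.21 CPM and from 26.8 ± 0.810 to 83.0 ± 6.94 CPM, while the protease gene Adamts1 fell from 427 ± 17.5 to 222 ± 6.14 CPM. Of the fibroblast and meningeal markers, 11 of 17 rose beside this list. Synapse-regulating factors of astrocytes numbered 11 higher and 7 lower of 24 (median 0.12, camera adjusted p = 0.29). The proteoglycan gene Vcan rose from 125 ± 11.2 to 364 ± 14.5 CPM, Thbs2, a thrombospondin, from 287 ± 7.47 to 553 ± 18.8 CPM and Tnc, tenascin C, from 3116 ± 136 to 4717 ± 68.3 CPM, and Gpc4, glypican 4, fell from 369 ± 7.22 to 217 ± 6.25 CPM.

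Interferon-stimulated genes rose without exception: all 34 were higher, with a median log2 fold change of 1.23 (camera adjusted p = 2.0e-24; adjusted p = 0.084 with an estimated correlation). The antiviral genes Mx1 and Rsad2 rose from 28.4 ± 1.80 to 155 ± 8.73 CPM (2.44) and from 258 ± 7.11 to 876 ± 43.3 CPM (1.77), Ifit2 from 228 ± 7.71 to 981 ± 68.0 CPM (2.10) and Ifi44 from 103 ± 4.44 to 445 ± 35.6 CPM (2.11). Proliferation genes fell as a group, 1 higher and 24 lower of 34 (1 and 26 adjusted over the list alone; median −0.22, camera adjusted p = 8.3e-06; adjusted p = 0.11 with an estimated correlation). Aurkb, a mitotic kinase, fell from 28.7 ± 0.819 to 18.1 ± 0.599 CPM, Ube2c from 74.4 ± 2.36 to 51.5 ± 2.96 CPM and Rrm2, a ribonucleotide reductase subunit, from 184 ± 5.76 to 136 ± 4.34 CPM; the kinesin gene Cenpe rose from 57.3 ± 3.65 to 85.0 ± 5.07 CPM. Immediate-early genes, which respond within minutes to stimulation, numbered 0 higher and 16 lower of 24 (1 and 16 adjusted over the list alone; median −0.36, camera adjusted p = 7.1e-05; adjusted p = 0.33 with an estimated correlation). Klf2 fell from 37.0 ± 1.19 to 17.4 ± 1.69 CPM, Ier2 from 29.1 ± 0.993 to 14.7 ± 1.35 CPM and Dusp1 from 185 ± 7.64 to 110.3 ± 5.91 CPM.

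Markers of other cells that a cortical culture can hold differed as well. Microglia and macrophage markers numbered 1 higher and 18 lower of 23 (median −0.92, camera adjusted p = 9.4e-07; adjusted p = 0.084 with an estimated correlation). Lyz2 fell from 328 ± 6.81 to 189.8 ± 8.74 CPM and C1qc from 7.93 ± 1.14 to 2.99 ± 0.154 CPM; Lyz2 is 95.8% identical to Lyz1 over 1264 bases. Fibroblast and meningeal markers numbered 11 higher and 3 lower of 17 (median 0.59, camera adjusted p = 0.0029; adjusted p = 0.13 with an estimated correlation). The collagen gene Col3a1 rose from 253 ± 2.71 to 496 ± 7.79 CPM, and the proteoglycan genes Dcn and Lum from 14.7 ± 0.934 to 43.4 ± 0.468 CPM and from 3.24 ± 0.112 to 10.4 ± 0.460 CPM; these rose beside the matrix list. Ependymal markers numbered 1 higher and 5 lower of 13 (1 and 6 adjusted over the list alone; median −0.43, camera adjusted p = 0.020; adjusted p = 0.17 with an estimated correlation), and this call was lost on DESeq2 (adjusted p = 0.14) and limma-voom values (0.066). Without knockout replicate 3 the ependymal median was −0.28. Foxj1, a regulator of motile cilia, fell from 60.7 ± 1.39 to 33.2 ± 3.93 CPM.

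Markers of 5 further cell types were not called as groups. Endothelial markers numbered 6 higher and 1 lower of 14 (median 0.36, camera adjusted p = 0.15); Cdh5 and Flt1 rose from 26.8 ± 0.439 to 53.4 ± 1.93 CPM and from 43.5 ± 2.87 to 68.1 ± 1.37 CPM, and Slco1a4 fell from 13.2 ± 0.845 to 3.70 ± 0.478 CPM. The endothelial median was 0.21 without control replicate 1 and 0.13 without knockout replicate 2. Pericyte and smooth muscle markers numbered 3 higher and 6 lower of 12 (median −0.36, camera adjusted p = 0.084, and 0.0025 on DESeq2 values); the contractile genes Cnn1 and Acta2 fell from 262 ± 10.2 to 119.8 ± 1.70 CPM and from 3849.9 ± 106 to 2685 ± 29.4 CPM, and Pdgfrb rose from 80.3 ± 3.17 to 115 ± 3.56 CPM. The median of this list was −0.17 with no filter, −0.21 without control replicate 3 and −0.12 without knockout replicate 1. Neuronal markers numbered 2 higher and 6 lower of 19 (median −0.19, camera adjusted p = 0.41), among them Stmn2, which fell from 284 ± 8.35 to 225 ± 9.11 CPM. The neuronal median was −0.092, −0.13 and −0.10 without control replicate 3, knockout replicate 1 and knockout replicate 2. Oligodendrocyte lineage markers numbered 3 higher and 6 lower of 14 (median −0.36, camera adjusted p = 0.41); Olig1 fell from 84.4 ± 3.20 to 46.4 ± 5.62 CPM and Pdgfra rose from 7.64 ± 0.598 to 14.1 ± 0.585 CPM. The oligodendrocyte median was −0.16 without control replicate 3. Neural progenitor markers numbered 3 higher and 6 lower of 17 (median −0.01, camera adjusted p = 0.61), with Nes, nestin, falling from 1117 ± 24.2 to 729.6 ± 1.496 CPM. That median was positive under a stricter filter and without control replicate 3, knockout replicate 1 or knockout replicate 2.

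Of the Y-linked genes and Xist, 4 rose and 0 fell of 5 (median 0.44, camera adjusted p = 0.044; adjusted p = 0.33 with an estimated correlation). Leaving out control replicate 1, control replicate 2 or knockout replicate 1 raised its adjusted p to 0.062, 0.054 and 0.097, and a replicate block to 0.054. Ddx3y rose from 67.0 ± 2.22 to 114 ± 2.47 CPM, while Xist, the transcript of the inactive X chromosome, had at most 35 counts in any library.

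**Figure D3:**
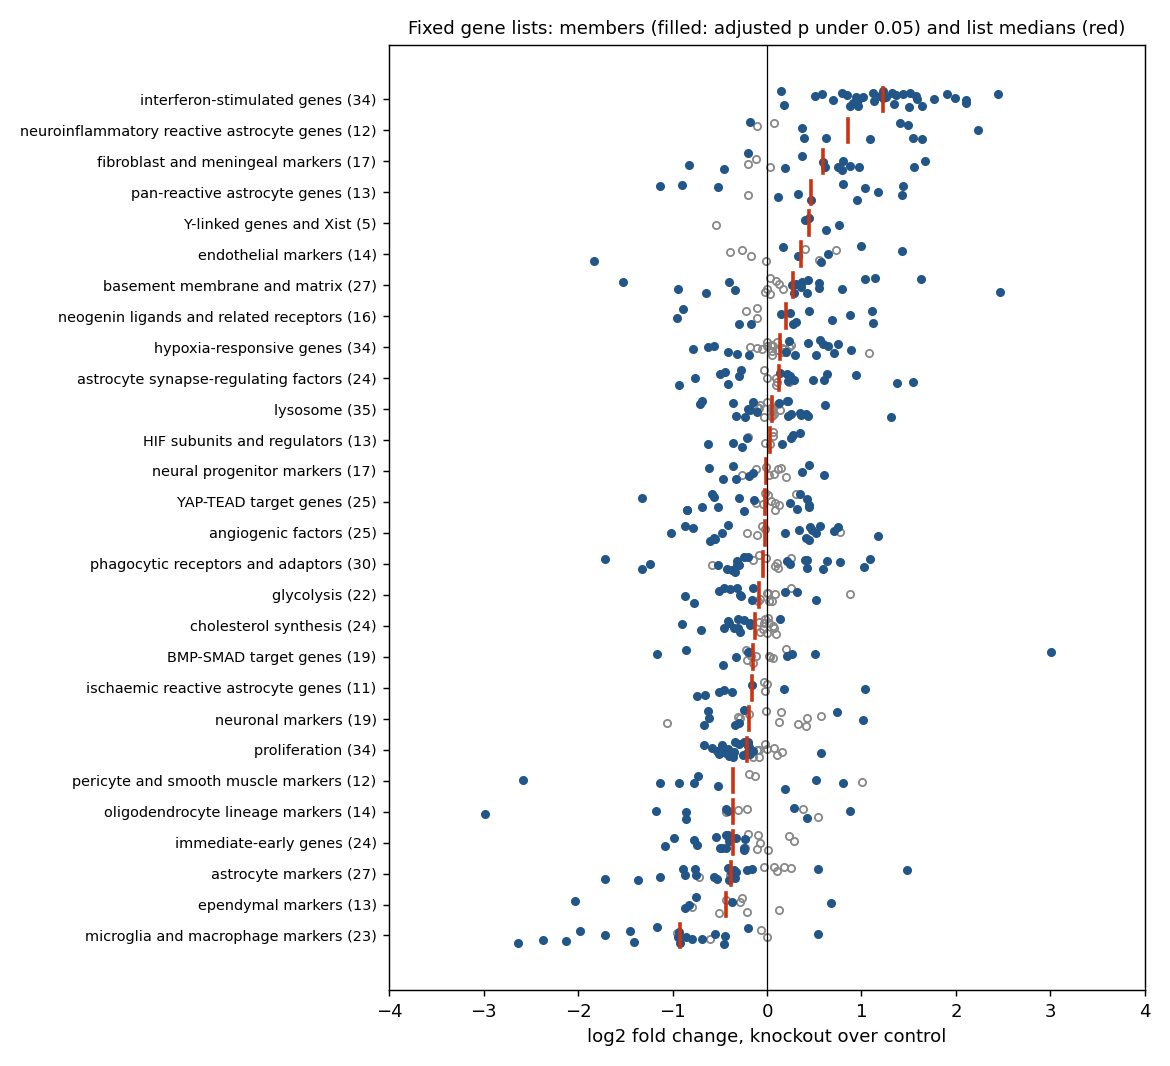
Log2 fold changes of knockout over control for the tested members of the 28 gene lists, with the number of members in brackets; filled points have an adjusted p under 0.05 and red bars are list medians. The list of interferon-stimulated genes has the highest median (1.23) and the list of microglia and macrophage markers the lowest (−0.92).

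Precision followed expression level. The median coefficient of variation within control and knockout cultures was 3.48% and 3.65% for genes above a mean log2 CPM of 6, and 38.3% and 40.8% for those below 0. Counts were simulated for 3 libraries per group at these depths and spreads, with 50 genes per size. There the test recovered 74% of genes changed 2-fold and 44% of those changed 1.5-fold, so small changes of weakly expressed genes were often missed. A far smaller share of genes was changed there than was called in the real data. The adjusted threshold was therefore stricter, and these rates may understate the recovery of the reported fit.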

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

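Scaling by total counts was chosen after the data were seen; all other settings were planned. Across the settings that refit the genes at an adjusted p of 0.05, the genes higher in knockout ran from 2907 to 3772 and the genes lower from 2753 to 4499, and no gene called in the reported fit was called in the opposite direction. A threshold of 0.01 left 2712 higher and 2467 lower. The log2 fold change of Neo1 ran from −0.95 to −0.87, Hif1a from 0.19 to 0.28, Epas1 from 0.28 to 0.37, Vegfa from 0.50 to 0.59 and Megf10 from −0.59 to −0.45. Tested against a fold of 1.5, 666 genes were higher and 348 lower, since small changes no longer counted. Camera called 12 gene lists, and 0 (8 at an unadjusted p under 0.05) with the correlation estimated from the data. Fry, which does not compare a list with other genes, called 21. An estimated correlation also leaves camera fewer degrees of freedom, and the 2 changes were not tested apart. The unadjusted camera p of the microglia list went from 6.7e-08 to 0.0040 with the estimated correlation. Estimated correlations were −0.013 for microglia, 0.014 for astrocyte and −0.014 for cholesterol synthesis lists, near the preset of 0.01. For these lists, that argues against correlated members as the cause of the lost calls. The estimates were 0.17 for interferon-stimulated and 0.34 for immediate-early genes. Leaving out 1 library gave 2907 to 3517 higher, 2753 to 3431 lower and 11 to 13 lists called.

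The replicate numbers shared by the genotypes showed no sign of pairing: same-numbered libraries deviated from their group means with correlations of 0.0151, 0.0194 and −0.00821. For libraries with different numbers the correlations ran from −0.0219 to 0.0126. With 3 libraries per group, this does not exclude a litter or culture shared by same-numbered libraries. With replicate number as a block, 3501 genes were higher and 3383 lower, and 11 lists were called. The block ended the call of the Y-linked genes and Xist (adjusted p = 0.054) and, of the lists called, no other.

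List medians near 0 changed sign, with the cause not tested. The angiogenic median was 0.022 under limma-voom, 0.075 under the filter of 1 CPM in 3 libraries, 0.024 under the replicate block, and from −0.054 to 0.20 without 1 library. The HIF subunits and regulators median was −0.031 under total-count scaling and from −0.011 to 0.084 without 1 library, and the lysosome median −0.0086 under total-count scaling. The YAP-TEAD median ran from −0.047 to 0.025 and the neural progenitor median from −0.037 to 0.047 without 1 library, the latter being 0.0085 under the filter of 1 CPM in 3 libraries. Of 120 other named genes, only Dynlrb2 lost its call, without control replicate 2 (adjusted p = 0.052). List calls were lost in 6 cases (ependymal markers under DESeq2 and limma-voom; the Y-linked genes and Xist under the block and without control replicate 1, control replicate 2 or knockout replicate 1) and gained in 6 (glycolysis under DESeq2, limma-voom and without control replicate 3; YAP-TEAD and pericyte lists under DESeq2; the hypoxia-responsive list with no filter). List calls under DESeq2 came from the pre-ranked form of camera, so a change of list test and of gene model cannot be told apart there. In the simulated data, where the adjusted threshold was stricter, 5.56% of genes changed 1.1-fold were recovered at a mean log2 CPM of at least 1.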

Other observations

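The 6 gene lists described first were written after the largest changes had been seen, as were the tests of immune cells and of a shared batch against the interferon pattern and the test of a lower microglial share; the other tests were written before their results were seen. Genes first named here were chosen after their values were seen. No list p-value is given for these 6 lists, because they were chosen with the changes in view, so their counts and medians are descriptive. Interferon-inducible GTPases, which act against intracellular pathogens, were all higher in the knockout cultures, 17 of 17 (17 adjusted over the list alone), with a median log2 fold change of 1.92; Gbp4 and Gbp10, among the 10 largest rises, are in this list. Gbp9 rose from 38.3 ± 2.51 to 221 ± 13.5 CPM and Gbp3 from 189.7 ± 5.12 to 538 ± 28.1 CPM. Genes of antigen processing for MHC class I were higher in 14 of 14 (14 adjusted over the list alone; median 0.82). The transactivator gene Nlrc5 rose from 28.6 ± 2.83 to 77.1 ± 3.90 CPM, B2m, the light chain of class I molecules, from 457 ± 11.5 to 838 ± 15.9 CPM and the immunoproteasome gene Psmb8 from 46.5 ± 0.937 to 99.2 ± 6.07 CPM. Of 22 H2 genes tested on chromosome 17, 16 were higher and 2, H2-Q1 and H2-DMb2, lower.

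Secreted factors and proteases also moved. Chemokines and cytokines numbered 21 higher and 7 lower of 30 (22 and 7 adjusted over the list alone; median 0.73). Ccl5, a T cell chemoattractant, rose from 111 ± 7.59 to 595 ± 10.03 CPM, Il6 from 88.9 ± 4.58 to 219 ± 27.2 CPM and Tslp from 5.18 ± 0.302 to 31.8 ± 2.14 CPM, whereas Tnf fell from 151 ± 4.96 to 43.7 ± 2.95 CPM, Il1b from 145 ± 6.36 to 86.9 ± 8.52 CPM and Il12b from 19.8 ± 1.22 to 9.10 ± 0.825 CPM; microglia and macrophage markers fell beside them, 18 of 23 (median −0.92). Cxcl10, an interferon-induced chemokine, was abundant in both genotypes and rose from 2089 ± 39.1 to 3649 ± 164 CPM. Nos2, inducible nitric oxide synthase, rose from 46.3 ± 1.64 to 238 ± 3.98 CPM. Matrix metalloproteinases numbered 10 higher and 2 lower of 15 (11 and 3 adjusted over the list alone; median 0.39), with Mmp3 rising from 255 ± 8.62 to 1248 ± 108 CPM and Mmp13 from 23.7 ± 0.656 to 116 ± 6.84 CPM; fibroblast and meningeal markers rose beside them, 11 of 17 (median 0.59). Ribosomal protein genes numbered 11 higher and 0 lower of 20 (13 and 0 adjusted over the list alone; median 0.15). Choroid plexus markers, among which Ttr was not counted, numbered 3 higher and 5 lower of 14 (3 and 6 adjusted over the list alone; median −0.27). Enpp2 rose from 18.5 ± 0.508 to 59.0 ± 2.57 CPM, and Otx2 and Sulf1 rose too. Folr1 fell from 6.52 ± 0.361 to 3.22 ± 0.399 CPM and 1500015O10Rik from 98.5 ± 7.69 to 54.1 ± 2.09 CPM. Col9a3 fell too, as did Kl and Clic6, which were at 0.529 ± 0.0907 and 0.622 ± 0.208 CPM in control cultures. The log2 fold change of Kl, the largest of these falls, was −2.50, against −10.44 for Ttr. Of the related engulfment receptors Axl, Tyro3 and Mertk and their ligands Gas6 and Pros1, Axl rose from 542 ± 2.79 to 726 ± 7.56 CPM and Pros1 from 109.9 ± 4.20 to 127 ± 2.82 CPM, Tyro3 fell from 27.6 ± 2.27 to 22.1 ± 1.34 CPM and Gas6 from 226 ± 5.85 to 181 ± 9.69 CPM, and Mertk was at 12.4 ± 1.30 CPM in control and 11.2 ± 1.06 CPM in knockout cultures (log2 fold change −0.15, adjusted p = 0.31, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

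All 34 interferon-stimulated genes were higher in knockout cultures. Microglia and macrophage markers, which share no gene with that list, had a median log2 fold change of −0.92. This argues against added microglia or macrophages as the source, and other immune cells were not tested. The lowest median of the interferon-stimulated genes over 3 other scalings was 1.16, which argues against scaling. No label names a culture or preparation batch, and the chi-square per gene between knockout libraries (5.996 for the closest pair, 19.6 and 22.2 for the others, against 153 or more between genotypes) would come out alike under a batch and under the genotype, so it decides nothing. The design statement calls the controls littermates but does not say which libraries shared a litter or culture, so a batch shared by the knockout libraries cannot be told apart from the genotype. A response of astrocytes to the loss of neogenin is the biological candidate explanation and was not tested separately.

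Microglia and macrophage markers were lower, and 94.1% of the 17 tested markers restricted to these cells (16) had log2 fold changes below 0. A lower share of these cells would give this. The test was written after the fall of the list was seen, so it adds no separate evidence. The log2 fold changes of these markers had an SD of 2.51 times their root mean square standard error. This argues against a lower share as the only change, but only if no other cells in the cultures express the markers. Tmem119, one of them, rose from 4.66 ± 0.458 to 6.76 ± 0.288 CPM, and whether other cells express it was not examined. Dilution by other cells stays open: the astrocyte marker median lay 0.556 above that of the restricted markers, with a 95% bootstrap interval of 0.207 to 1.09 that spans the limit of 0.3 set beforehand. The bootstrap resampled marker genes and not libraries, so the interval leaves out the spread between cultures. Of the 24 markers in the list, 4 are also in other lists, and how many of the rest astrocytes express was not examined. Lyz2 was at 328 ± 6.81 CPM in control and 189.8 ± 8.74 CPM in knockout cultures and Csf1r at 16.1 ± 1.53 CPM in control and 8.47 ± 0.129 CPM in knockout cultures, and a lower microglial share may follow from either genotype or culture.

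Near-identical copies of Eno1 and Rps18 were far lower in knockout cultures: Eno1b and the processed pseudogene Gm4735 together went from 315 ± 24.9 to 21.9 ± 1.55 CPM, and Gm11361 from 58.7 ± 3.02 to 5.13 ± 0.926 CPM. Eno1 did not gain as its copies fell, but changed by −0.344 CPM per CPM its copies lost (from 968 ± 43.4 to 867 ± 17.7 CPM). This argues against reads moving back to Eno1 only if its own expression was unchanged. Eno1 and its copies summed fell from 1283 ± 67.9 to 889 ± 19.2 CPM. Glycolysis genes numbered 3 higher and 10 lower of 22, so a fall of Eno1 itself could hide such a move. For Rps18 the parent gained 4.11 CPM per CPM lost (from 175 ± 7.53 to 395 ± 11.5 CPM), so the counted reads lost by its copy could account for part of its rise only. The rule for reads that map to several places is not given, so reads left uncounted could add to it. Processed pseudogenes were 3 of 77 called genes with a fold of at least 4 (odds ratio 1.65, one-sided Fisher's exact p = 0.28). Eno1b and Gm11361 are annotated as protein-coding and were not counted as pseudogenes, so this test misses such copies. A general effect of copies stays open. A candidate explanation, a sequence difference between the 2 groups at these loci, at Ttr or in the H2 region, where Rps18 (chromosome 17, 33951999 to 33956001) lies near H2-K2 and H2-K1, was not tested because the reads were not used here.

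Genes within 5 Mb of Neo1 were not called more often than others (42 of 116, 36.2% against 38.3%, odds ratio 0.915, two-sided Fisher's exact p = 0.70). With so many genes called elsewhere, this count could miss a flanking interval that differs between the groups, so it does not exclude one. The control library names point to the floxed gene too, in which case both groups would carry the same interval. The 6 libraries can be split into 3 and 3 in 10 ways, and 1 split, the real one, called as many as 7093 genes, while the highest of the others called 0 by edgeR's quasi-likelihood test, the only tool run on them (141 to 319 genes at an unadjusted p under 0.05, against 8465); 10 splits are too few for a share under 0.05. All 4 Y-linked genes measured rose, Ddx3y from 67.0 ± 2.22 to 114 ± 2.47 CPM, Uty from 16.1 ± 1.68 to 24.7 ± 2.67 CPM, Eif2s3y from 37.0 ± 1.46 to 49.0 ± 5.11 CPM and Kdm5d from 18.1 ± 1.20 to 24.7 ± 3.498 CPM, with Xist at 2 to 35 counts in each library.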
